A study of Mus musculus with 3 samples.

How the data were processed

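Non-parenchymal liver cells of female BALB/c mice were measured in 3 droplet libraries, 1 each for the PBS control, day 4 and day 21 after orthotopic injection of 4T1 cells. Each library came as a matrix of raw UMI counts for 31053 genes, with its barcodes and gene names, made with Cell Ranger 3.1.0 per the file headers and with the mm10 build per the submitters' processing notes. The deposited counts had already been restricted to barcodes called as cells, and any further step is not given in the sources used here. The smallest barcode held 500 UMIs. Gene positions came from GENCODE M21 on GRCm38, the gene set of Ensembl 96, in which 30934 of the 31053 gene IDs were found. The labels do not state how many mice were pooled per library, when in the day livers were collected, or the day of the control. Before the data were examined, the cell filters, class markers, gene lists, comparisons, rule for named genes and 19 alternative settings were fixed.

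Barcodes with at least 200 genes and at most 20% mitochondrial UMIs were kept, which removed 27.0% of control, 39.96% of day 4 and 13.5% of day 21 barcodes. The mitochondrial limit alone was exceeded by 23.8, 31.99 and 10.7%. Doublets, droplets that hold more than 1 cell, were scored with Scrublet as included in Scanpy at an expected rate of 0.8% per 1000 barcodes. Its automatic threshold marked 41 (0.866%), 107 (1.94%) and 661 cells (6.195%), against expected rates of 5.19, 7.34 and 9.87%, and these were removed. Where it marked under 0.5%, the highest-scoring expected share was to be removed instead, which applied only without a cell filter, to 324 control and 640 day 4 barcodes. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, 30 principal components, a graph of 15 neighbours and Leiden clustering at resolution 1 gave 36 clusters, with no integration of the libraries. The tools were Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.

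Clusters were named from 20 marker lists. A marker counted as detected when at least 10% of the cells of a cluster held it and its level was 2-fold or more over the other clusters. A name needed at least 3 detected markers, more than any other class, and no other class with more markers, or as many where there were any, among the 10 leading genes of the cluster. Clusters 5 and 9 (endothelial-like, 13 detected markers) and 24 (stellate-like, 12) had 0 among those 10. A shallow cluster with no marker among those 10 stayed unnamed. In cells simulated from the summed profiles of the 13 named classes, 12 classes took their own name and 1 stayed unnamed. As the same markers had named those classes, this checks the working of the step and not whether the names are right. The marker lists of cholangiocytes, mesothelial, plasma, eosinophil, erythroid, megakaryocyte/platelet and 4T1-type epithelial tumour cells named no cluster in the main setting. The other 13 named the classes whose shares the report gives.

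Shares are of all kept cells, with exact Clopper-Pearson intervals, and ratios of shares carry a log risk ratio interval with 0.5 added to each count. For expression, raw counts were summed over the cells of a class in a library and expressed as CPM of that sum. Log2 ratios add 0.5 counts to each sum and carry an exact conditional binomial interval. A gene with 0 counts in a library is given as a bound against a floor of 3 counts in the class sum. Only classes with 50 or more cells in both libraries were compared, which left out monocyte/macrophage-like cells. Each of 28 gene lists was summarised by the median over members with 20 or more UMIs in the libraries compared. Its interval came from 2000 Poisson resamples, and its percentile from 10000 random lists of equal size matched in 20 bins of expression. Some list members also served to name the classes. Among granule genes these were Elane, Mpo, Prtn3, Ctsg, Camp, Ngp, Ltf, Lcn2, Mmp8 and Mmp9. Among Kupffer identity genes they were Clec4f, Timd4, Vsig4, Cd5l, Marco, Folr2, Cd163, Slc40a1 and Fabp7. The medians of these lists within such classes therefore depend in part on the naming. As there is 1 library per group, no test between groups, p-value or count of changed genes was computed, and the intervals leave out variation between mice. Those of genes and lists also leave out variation between cells.

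For each comparison with the control, the report names the 5 genes with the largest and the 5 with the smallest log2 ratio in Kupffer-like, endothelial-like and neutrophil-like cells. Such a gene needed 50 or more UMIs, detection in at least 10% of cells of the higher library, and at least 0.25 of the level in the class where it was highest, a guard against free RNA. A named gene and some list examples are not reported here. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and unnamed genes were left out. Of the 387 list and class pairs computed against the control, the 81 in the report were picked after their values had been seen, as were the examples of each list and the 6 genes given with a position. The pairs called opposite between days were those reported in both comparisons (31) with intervals on opposite sides of 0 and percentiles up to 2.5 or from 97.5, bounds also set afterwards.

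The expression step was tested on simulated counts with 200 genes altered. For a planted 2-fold and 4-fold increase, the day 4 comparison returned median log2 ratios of 0.96 and 1.957 among 9236 Kupffer-like genes, 0.96 and 1.98 among 10141 endothelial-like genes, and 0.89 and 1.84 among 1066 neutrophil-like genes. The day 21 comparison returned 0.94 and 1.94 among 7872 Kupffer-like genes, 0.97 and 1.99 among 9611 endothelial-like genes, and 0.95 and 1.70 among 5018 neutrophil-like genes. In neutrophil-like cells the interval lay on the right side of 0 for 76.0% of 2-fold and 100% of 4-fold increases at day 4, and for 22% and 50% at day 21, where genes left alone had a median of -0.15.

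The alternatives for shares were a stricter filter (500 genes and 10% mitochondrial UMIs), no filter, doublets kept, resolutions 0.5 and 2, classes from each cell's own markers, libraries drawn down to 4693 cells, and haematopoietic classes alone. The last counts named haematopoietic classes as the total and leaves out all unnamed clusters, also those with haematopoietic markers. Those for expression were size factors from the median of ratios, no minimum or a minimum of 100 UMIs, 5 counts added, cells thinned to 1000 UMIs, and the mean over cells of per-cell CPM. Doublets kept and the stricter filter were repeated there. Members under 0.25 of the highest class were left out, free RNA was subtracted, and haemoglobin, immunoglobulin, mitochondrial and ribosomal genes were left out of the total. After the data had been seen, 5 more were added: each hepatocyte cluster alone, the low-UMI cluster counted as endothelial, all granulocytic clusters combined, monocyte/macrophage cluster 14 alone, and neutrophil cluster 2 alone.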

Results

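The series asked how a tumour growing outside the liver alters the cells of the liver, its inflammatory state and the metabolic programme governed by the transcription factor HNF4A. Non-parenchymal cells, the fraction left after most hepatocytes are removed, were obtained from perfused and dissociated livers of female BALB/c mice and profiled by 10x droplet 3' single-cell RNA sequencing. The 3 libraries, 1 per group, came from a PBS-injected control and from mice given 4T1 cells, a mammary carcinoma line of BALB/c origin, 4 or 21 days before collection. The control and the day 4 library were labelled 8 weeks of age and the day 21 library 11 weeks, and neither the number of mice per library nor the collection day of the control was stated. The control held 6489 barcodes and 27191082 UMIs (unique molecular identifiers, each counting 1 captured transcript), the day 4 library 9175 barcodes and 34833820 UMIs, and the day 21 library 12338 barcodes and 51913215 UMIs. After filtering, 4693, 5402 and 10009 cells remained, with median depths of 4179, 4436 and 3030 UMIs per cell.

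The cells formed 36 clusters, of which 27 took 1 of 13 class names from fixed markers. No cluster took the name of cholangiocytes, mesothelial, plasma, eosinophil, erythroid, megakaryocyte or 4T1-type epithelial tumour cells. The tumour keratinocyte genes Krt14 and Krt6a and the cornified envelope gene Sprr1a had 0 UMIs in each library. Of the other 7 marker genes of that type, Krt8, Krt18, Epcam, Cldn4, Cdh1 and Lgals7 were detected in each library, with 466, 744 and 448 UMIs of Krt8, 361, 453 and 174 of Epcam and 24, 81 and 10 of Lgals7 in the control, at day 4 and at day 21. Wnt7b had 0, 2 and 2. With 1 library per group there is no replicate check and no test between groups. Each percentage below carries an exact 95% binomial interval, and each ratio a 95% interval, all covering counting error only. After a gene name, the values in parentheses are the level in the control, the level in the tumour library, the log2 ratio of tumour over control and its interval. A list is described by the median log2 ratio of its measured members, its interval, and its percentile among 10000 random lists of matched expression. The heat shock genes Hspa1a and Hspa1b, and the pairs Saa1 and Saa2, Orm1 and Orm2, Ifit3 and Ifit3b, and Stfa2 and Stfa3, are near-identical, so their separate counts are uncertain.

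**Figure D1:**
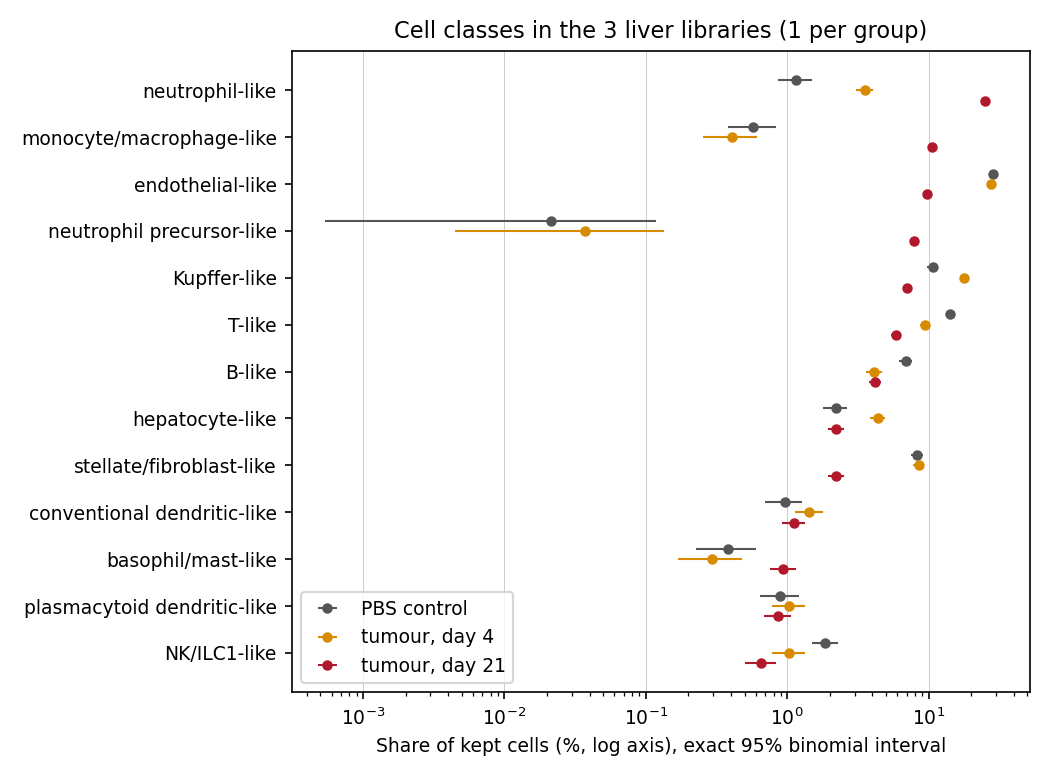
Share of kept cells in each class, in percent on a log axis, for the control, day 4 and day 21 libraries, with 1 point per library and exact 95% binomial intervals as bars. Neutrophil-like cells stood at 1.15, 3.54 and 25.2%, and endothelial-like cells at 28.7, 27.6 and 9.77%.

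The comparison of day 4 with the control addresses the early response of the liver to a tumour elsewhere in the body. Neutrophil-like cells made up 3.54% (3.06 to 4.06) of cells at day 4 and 1.15% (0.866 to 1.50) in the control, a 3.05-fold (2.27 to 4.11) higher share. Kupffer-like cells, the resident macrophages of the liver, were 1.67-fold (1.51 to 1.85) higher, at 17.8 against 10.7%. Genes induced by type I interferon, an antiviral cytokine family, were higher together in Kupffer-like, endothelial-like, neutrophil-like, T-like and stellate-like cells, and genes of mitosis were higher in T-like cells. In Kupffer-like cells the chemokines Cxcl1 and Cxcl2, which attract neutrophils, were 7.22- and 4.91-fold lower than in the control.

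Among the other classes, hepatocyte-like cells were 1.98-fold (1.57 to 2.48) and conventional dendritic-like cells 1.48-fold (1.03 to 2.13) higher in share at day 4. T-like cells (0.665-fold, 0.597 to 0.741), B-like cells (0.591-fold, 0.501 to 0.698) and NK/ILC1-like cells (0.561-fold, 0.402 to 0.782) had lower shares. NK/ILC1-like cells were close to the control when called doublets were kept (log2 ratio -0.16) or when classes came from each cell's own markers (-0.04). Cluster 26, led by Gzmb, Ccl5 and Xcl1, stayed unnamed because 8 markers each of NK/ILC1 and T cells were detected. It held 1.34% of control and 1.83% of day 4 cells, so the lower NK/ILC1-like share holds for the named cluster alone. The ratio included 1 within its interval for endothelial-like (0.960-fold, 0.902 to 1.02), stellate-like (1.03-fold, 0.905 to 1.17), plasmacytoid dendritic-like (1.15-fold, 0.777 to 1.72), monocyte/macrophage-like (0.711-fold, 0.408 to 1.24) and basophil/mast-like cells (0.775-fold, 0.399 to 1.50). For stellate-like and plasmacytoid dendritic-like cells it fell on the other side of 1 without a cell filter (log2 ratios -0.20 and -0.08), and for monocyte/macrophage-like cells the log2 ratio was then -1.44 against -0.49. Neutrophil precursor-like cells numbered 1 in the control and 2 at day 4. Unnamed clusters held 23.2% of control and 20.4% of day 4 cells, mostly a low-UMI cluster with endothelial markers (17.5 and 12.1%). Endothelial-like cells with that cluster added made up 46.3 and 39.7%.

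In Kupffer-like cells at day 4, the type I interferon list had a median log2 ratio of 0.27 (0.23 to 0.37, percentile 100), with 0 of 15 measured members at least 2-fold higher and 0 at least 2-fold lower. Examples were Zbp1 (67.2 and 96.5 CPM, 0.52, 0.31 to 0.74), Oasl2 (73.0 and 94.9 CPM, 0.38, 0.17 to 0.59) and Irf7 (907 and 1157 CPM, 0.35, 0.29 to 0.41), a nucleic acid sensor, an oligoadenylate synthetase-like protein and the transcription factor that amplifies interferon production. The interferon gamma list stood at 0.29 (0.23 to 0.52, percentile 100), with 3 of 16 measured members at least 2-fold higher and 0 at least 2-fold lower. Its largest ratios were those of the interferon-inducible GTPases Iigp1 (36.1 and 77.7 CPM, 1.10, 0.83 to 1.39) and Igtp (18.4 and 38.3 CPM, 1.05, 0.66 to 1.46). The 5 genes with the largest ratios of the class included Irgm2 (14.0 and 43.1 CPM, 1.61, 1.19 to 2.08), a GTPase of the same family, and Fpr1 (54.8 and 139 CPM, 1.34, 1.13 to 1.57), a receptor for bacterial formyl peptides. They also included Il10ra (50.7 and 118 CPM, 1.22, 0.99 to 1.46), a subunit of the interleukin 10 receptor, and Fam111a (29.7 and 76.2 CPM, 1.35, 1.06 to 1.67). The chaperone gene Hspa1b (5.23 and 25.2 CPM, 2.23, 1.58 to 3.03) had the largest, and its log2 ratio was 4.59 with each cell thinned to 1000 UMIs. The log2 ratio of Fam111a was 0.62 in thinned cells. Kupffer identity genes, many of them also markers of the class, were slightly higher (0.16, 0.13 to 0.20, percentile 99.9), with 17 of 17 members between 2-fold lower and 2-fold higher. The transcription regulators Spic (58.1 and 98.3 CPM, 0.76, 0.53 to 0.99), Id1 (108 and 179 CPM, 0.72, 0.56 to 0.89) and Id3 (357 and 567 CPM, 0.67, 0.58 to 0.76) were the examples. MHC class II genes had a median of 0.14 (0.11 to 0.21, percentile 97.0).

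The lowest ratio in Kupffer-like cells was that of Cxcl1 (57.8 and 7.95 CPM, -2.85, -3.32 to -2.43), followed by the cell cycle inhibitor Cdkn1a (277 and 41.1 CPM, -2.75, -2.95 to -2.56) and Cxcl2 (991 and 202 CPM, -2.29, -2.38 to -2.21). Next came Cytip (272 and 56.4 CPM, -2.27, -2.44 to -2.10). The list of inflammatory cytokines and chemokines stood at 0.09 (0.01 to 0.19, percentile 86.9) and went both ways, with 2 of 15 measured members at least 2-fold higher and 5 at least 2-fold lower. The monocyte attractant Ccl2 (4.13 and 12.2 CPM, 1.52, 0.75 to 2.46) was among the higher members. Immunosuppressive myeloid genes were lower (-0.23, -0.40 to -0.17, percentile 0.655), with Il10 (41.0 and 11.6 CPM, -1.82, -2.24 to -1.43) and the inhibitory receptor gene Havcr2 (13.2 and 6.36 CPM, -1.05, -1.68 to -0.43). G2/M genes were lower (-0.95, -1.12 to -0.66, percentile 0), as Ube2c (35.2 and 11.4 CPM, -1.62, -2.05 to -1.21) and Nusap1 (10.5 and 3.47 CPM, -1.58, -2.39 to -0.82) show. Immediate early and dissociation-linked genes were lower (-0.38, -0.45 to -0.32, percentile 0), with Egr1 (109 and 39.2 CPM, -1.48, -1.71 to -1.25). The chaperone members Hspa1a and Hspa1b of that list were higher. Lipid-associated macrophage genes (0.00, -0.07 to 0.07, percentile 44.5) and iron and haem handling genes (-0.01, -0.05 to 0.05, percentile 39.8) had medians near 0 whose sign differed between settings, with the lipid receptor gene Trem2 (82.3 and 54.4 CPM, -0.60, -0.82 to -0.37) lower.

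Endothelial-like cells at day 4 had a median of 0.52 (0.40 to 0.62, percentile 100) for the type I interferon list, with 0 of 15 measured members at least 2-fold higher and 0 at least 2-fold lower. Its members included Oasl2 (59.1 and 97.8 CPM, 0.73, 0.56 to 0.90), Ifi44 (104 and 149.5 CPM, 0.53, 0.40 to 0.66) and Rsad2 (71.5 and 103 CPM, 0.52, 0.37 to 0.68). The interferon gamma list stood at 0.28 (0.14 to 0.35, percentile 100). Its member Cxcl10, a chemokine that attracts activated T cells (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889, minus strand, GRCm38), was 3.30-fold higher (27.6 and 91.1 CPM, log2 ratio 1.72, 1.50 to 1.95). The other genes with the largest ratios were the chaperones Hspa1b (6.99 and 35.4 CPM, 2.33, 1.92 to 2.79) and Hsph1 (22.6 and 61.8 CPM, 1.45, 1.201 to 1.71). The endoplasmic reticulum protein gene Sdf2l1 (45.5 and 124 CPM, 1.44, 1.27 to 1.62) and the homeobox gene Hoxb2 (10.7 and 34.3 CPM, 1.68, 1.32 to 2.05) completed them. The Hoxb2 log2 ratio was 0.73 in thinned cells. The lowest ratios belonged to Chka (123 and 26.3 CPM, -2.22, -2.44 to -2.003), which encodes choline kinase, and Ddit4 (202 and 52.9 CPM, -1.93, -2.09 to -1.78), an inhibitor of mTORC1 signalling. They were followed by Arrdc2 (36.7 and 10.2 CPM, -1.84, -2.22 to -1.48), Apold1 (73.8 and 21.2 CPM, -1.79, -2.05 to -1.55) and Rel (179.8 and 53.0 CPM, -1.76, -1.92 to -1.60), a subunit of NF-kB.

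Immediate early and dissociation-linked genes were lower in endothelial-like cells (-0.36, -0.50 to -0.31, percentile 0), including the flow-responsive factor Klf2 (1185 and 355 CPM, -1.74, -1.80 to -1.68). Fatty acid and cholesterol genes were slightly lower (-0.17, -0.24 to -0.01, percentile 0.310), with the fatty acid importer Cpt1a (65.3 and 45.6 CPM, -0.52, -0.71 to -0.32) as an example. Their median was 0.02 in thinned cells. Adhesion genes had a median of -0.01 (-0.05 to 0.08, percentile 36.5), with Vwf (31.6 and 16.4 CPM, -0.94, -1.26 to -0.63) and Icam2 (209.9 and 293 CPM, 0.48, 0.39 to 0.57) on opposite sides. Sinusoidal scavenger receptors stood at 0.00 (-0.03 to 0.03, percentile 55.8), with Clec4g (3994 and 4319 CPM, 0.11, 0.09 to 0.14). The sign of both medians differed between settings. Angiocrine factors (-0.05, -0.10 to 0.10, percentile 13.4) included the Notch ligand Dll4 (66.2 and 109 CPM, 0.72, 0.57 to 0.88), and their median was 0.16 after thinning. IL6-STAT3 genes stood at 0.04 (-0.04 to 0.17, percentile 63.2) and hypoxia genes at -0.05 (-0.18 to 0.06, percentile 14.5). Among the latter the peptide hormone gene Adm (84.2 and 34.5 CPM, -1.28, -1.50 to -1.08) was lower and the collagen prolyl hydroxylase gene P4ha1 (69.5 and 120.4 CPM, 0.79, 0.64 to 0.95) higher.

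Neutrophil-like cells at day 4 numbered 191, against 54 in the control with 75523 UMIs in all, so their intervals are wide. Ly6g, a neutrophil surface protein gene (ENSMUSG00000022582, chromosome 15, 75155240 to 75159126, plus strand, GRCm38), had 1 UMI in the control and 74 at day 4 (log2 ratio 3.49, 1.55 to 9.39). The log2 ratio was 0.27 when called doublets were kept. That setting also clustered the cells anew, with 57 control cells neutrophil-like and 0 precursor-like, against 54 and 1. All granulocytic clusters of the main setting together held 57 control cells. Lower values with doublets kept may thus reflect where a few control cells were placed, which was not traced. Granule protein genes, made early in neutrophil maturation and many of them also class markers, had a median of 1.34 (0.76 to 1.78, percentile 100). Against a floor of 3 counts, these were Ngp (0 and 1078 CPM, at least 27.1-fold higher), Camp (0 and 664 CPM, at least 16.7-fold higher) and Ltf (0 and 219 CPM, at least 5.52-fold higher), while Lcn2 (649 and 1652 CPM, 1.33, 0.93 to 1.80) was detected in both. Of the 191 day 4 cells, 6 lay in cluster 10, which held 0 control cells and at day 21 carried 15590 CPM of Ngp. A few such cells may carry much of the day 4 values of Ngp, Camp and Ltf. The unnamed granule-gene cluster 6, outside the class, held 2 control and 4 day 4 cells. With members at 0 set to their bound the list median was again 1.33. Keeping doublets turned that median to -0.74, and it was 0.46 in the only neutrophil cluster with 50 or more cells in each library. The type I interferon list stood at 1.37 (0.73 to 1.84, percentile 100), with Ifit2 at least 2.27-fold higher and Ifit1 (66.2 and 255 CPM, 1.82, 0.67 to 3.61). Its median was 0.997 with members at 0 set to their bound, and 0.40 under a stricter cell filter. Acute phase and alarmin genes were higher (0.65, 0.61 to 0.94, percentile 99.8), with the glycoprotein gene Lrg1 (649 and 1757 CPM, 1.42, 1.02 to 1.89) and S100a8 (44150 and 73160 CPM, 0.73, 0.68 to 0.78). With doublets kept their median was 0.15. The other largest ratios were those of Wfdc17 (371 and 2580 CPM, 2.77, 2.26 to 3.40) and the interferon-inducible genes Gbp2b (26.5 and 219 CPM, 2 UMIs in the control, log2 ratio 2.74, 1.15 to 6.12) and Trim30a (79.4 and 502 CPM, 2.55, 1.51 to 4.13). Over the other settings the Gbp2b log2 ratio ranged from 1.34 to 2.92. Prr5l had 3 UMIs in the control (39.7 and 234 CPM, log2 ratio 2.35, 0.96 to 4.87). Its log2 ratio was 1.59 under the stricter filter and 1.23 at its lowest over all settings. The lowest ratios were those of Nktr (331 and 78.1 CPM, -2.08, -2.93 to -1.23), the urokinase receptor gene Plaur (489.9 and 138 CPM, -1.83, -2.48 to -1.16) and the proton-sensing receptor gene Gpr65 (344 and 99.1 CPM, -1.80, -2.58 to -0.996). Then came the membrane linker gene Ezr (410.5 and 120.2 CPM, -1.78, -2.49 to -1.05), which joins membrane and actin, and Dennd4a (1470 and 448 CPM, -1.72, -2.08 to -1.35).

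In T-like cells at day 4, G2/M genes had a median of 1.01 (0.84 to 1.16, percentile 100), with 6 of 12 measured members at least 2-fold higher and 0 at least 2-fold lower. S phase genes stood at 0.68 (0.52 to 0.87, percentile 100), and at 0.27 as a mean over cells. Examples were Ccnb1 (3.89 and 18.0 CPM, 2.16, 1.19 to 3.38) and Birc5 (46.2 and 114 CPM, 1.30, 0.98 to 1.63), of mitosis, and the nucleotide synthesis genes Rrm2 (29.5 and 91.5 CPM, 1.62, 1.24 to 2.03) and Tyms (28.4 and 62.6 CPM, 1.14, 0.72 to 1.57). The cluster of cycling T-like cells, defined by such genes, held 7.34% of the class in the control (49 of 668 cells) and 9.79% at day 4 (50 of 511). The list intervals resample UMIs and leave out variation between these cells. Interferon gamma genes (0.39, 0.33 to 0.58, percentile 99.8) included Cxcl10 (2.72 and 32.0 CPM, 3.47, 2.44 to 4.92) and Gbp3 (14.4 and 30.2 CPM, 1.06, 0.47 to 1.69). Type I interferon genes (0.50, 0.37 to 0.71, percentile 99.9) included Ifi27l2a (872 and 1359 CPM, 0.64, 0.56 to 0.72). Naive lymphocyte genes were lower (-0.22, -0.31 to -0.15, percentile 0.830), with the lymph node homing receptor Ccr7 (317 and 204 CPM, -0.64, -0.81 to -0.47) and the interleukin 7 receptor Il7r (609 and 414 CPM, -0.56, -0.68 to -0.44). Cytotoxic genes had a median of 0.44 (-0.01 to 0.55, percentile 99.6), with Ifng (27.2 and 50.02 CPM, 0.87, 0.43 to 1.33), and -0.01 among members with 100 or more UMIs.

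Stellate-like cells at day 4 had higher extracellular matrix and activation genes (0.52, 0.43 to 0.61, percentile 100), with 1 of 12 measured members at least 2-fold higher and 0 at least 2-fold lower. Among them were the collagen gene Col1a1 (72.4 and 121 CPM, 0.74, 0.54 to 0.95) and the contractile gene Tagln (107 and 168 CPM, 0.65, 0.48 to 0.82). Type I interferon (0.21, 0.14 to 0.36, percentile 99.8) and interferon gamma genes (0.21, 0.11 to 0.33, percentile 99.9) were slightly higher, with Ifit1 (54.7 and 93.2 CPM, 0.77, 0.53 to 1.01) and Cxcl9 (32.4 and 81.0 CPM, 1.32, 1.03 to 1.62), but Cxcl10 (63.9 and 31.1 CPM, -1.04, -1.35 to -0.73) was lower. G2/M genes (-1.65, -1.82 to -1.07, percentile 0) and immediate early and dissociation-linked genes (-0.52, -0.60 to -0.45, percentile 0) were lower, with Tpx2 (7.28 and 2.15 CPM, -1.71, -3.02 to -0.65) and Egr1 (241 and 97.45 CPM, -1.31, -1.48 to -1.14). The G2/M median was -0.88 as a mean over cells. In hepatocyte-like cells, urea cycle genes were higher (0.92, 0.65 to 1.05, percentile 100), with Otc (153 and 391 CPM, 1.35, 1.07 to 1.65), Ass1 (655 and 1529 CPM, 1.22, 1.08 to 1.36) and Cps1 (449.7 and 950.3 CPM, 1.08, 0.91 to 1.25). Hnf4a stood at 130.1 CPM in the control and 166 CPM at day 4 (log2 ratio 0.35, 0.01 to 0.70). This class pooled cluster 18 and the deeper cluster 32, with medians of 1054 and 11574 UMIs per cell over the libraries. Cluster 32 also had all 10 cholangiocyte markers detected, beside 12 of hepatocytes, and Spp1 and Clu were its leading genes. It may therefore hold cells other than hepatocytes, and its deeper cells weigh more in summed counts. HNF4A-linked genes had a median of 0.13 (0.03 to 0.19, percentile 81.8), which turned to -0.08 with doublets kept and -0.03 under the stricter filter. Among them Cyp7a1 (43.8 and 116 CPM, 1.39, 0.87 to 1.97), the rate-limiting enzyme of bile acid synthesis, was higher, and Cyp2e1 (1861 and 1119 CPM, -0.73, -0.84 to -0.63) and Apoa1 (6379 and 3889 CPM, -0.71, -0.77 to -0.66), a cytochrome P450 and an apolipoprotein, were lower. Acute phase genes stood at 0.27 (-0.01 to 0.49, percentile 91.6), and ranged from 0.02 to 0.75 over the other settings. Free RNA was estimated at 12.9% of UMIs in stellate-like (19.9% in the control) and 5.47% in hepatocyte-like cells (5.62%), and the hepatocyte-like median depth was 2238 UMIs in the control and 1382 at day 4. The estimate is the level of other lineages' markers relative to all kept cells, so it does not separate free RNA from mixed droplets. Stellate cluster 23 also had 7 detected endothelial markers. It held 38.5% of the class in the control, 29.4% at day 4 and 0.4525% at day 21.

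The comparison of day 21 with the control addresses the liver at the later stage of tumour growth. Neutrophil-like cells made up 25.2% (24.4 to 26.1) of cells, a 21.7-fold (16.7 to 28.4) higher share than in the control, and monocyte/macrophage-like cells were 18.2-fold (12.5 to 26.5) higher. Of the latter, 50.7% lay in cluster 16, which held 0 control cells, and 91.5% of the cells there had the proliferation gene Mki67 and 77.7% the granule gene Elane. In cluster 14 alone, with all 27 control cells of the class and 525 at day 21, the share was 8.96-fold (6.12 to 13.1) higher, an alternative chosen after the data had been seen. Endothelial-like cells stood at a 0.340-fold (0.316 to 0.367) and stellate-like cells at a 0.268-fold (0.228 to 0.315) share relative to the control. In endothelial-like cells the adhesion molecules Sele, Selp and Vcam1, the STAT3 targets Socs3 and Bcl3 and immediate early and dissociation-linked genes were higher. Type I interferon genes were lower in endothelial-like, Kupffer-like, stellate-like and T-like cells. In hepatocyte-like cells the acute phase protein gene Saa1 was 21.4-fold (15.7 to 30.8) higher.

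Neutrophil precursor-like cells numbered 785 at day 21 (7.84%, 7.32 to 8.39) and 1 in the control, a 246-fold (49.5 to 1218) higher share. They made up 18.3% of day 21 cells with classes from each cell's own markers, 12.1% under the stricter filter, 5.44% at a coarser clustering and 4.90% at equal cell numbers. With 0 to 2 cells in the control under any setting, the log2 ratio ranged from 7.17 among haematopoietic classes to 9.55 without a cell filter. An unnamed cluster led by the granule genes Ltf, Camp and Ngp held 9.26% of day 21 and 0.0426% of control cells, and all granulocytic clusters together 42.3 and 1.21%. Another unnamed cluster, led by the progenitor genes Cd34, Cdk6 and Myb, held 392 cells at day 21 and 7 in the control, and 1 with the surrogate light chain genes of early B cells held 300 and 0. These clusters come almost wholly from 1 library, so whether other livers at day 21 hold such cells is not known here. Kupffer-like cells had a lower share (0.663-fold, 0.594 to 0.739), as did T-like (0.414-fold, 0.373 to 0.460) and NK/ILC1-like cells (0.351-fold, 0.255 to 0.483), and basophil/mast-like cells a higher one (2.40-fold, 1.46 to 3.94). Shares depend on one another. Per endothelial-like cell, hepatocyte-like (2.97 times the control), Kupffer-like (1.95), B-like (1.77) and T-like cells (1.22, 1.06 to 1.40) were higher, and stellate-like cells lower (0.787). B-like cells were lower in share (0.603-fold, 0.524 to 0.694), but the log2 ratio turned from -0.73 to 0.08 at a finer clustering, 0.07 with classes from each cell's own markers and 0.33 without a cell filter. In these 3 settings the class held 717, 709 and 794 day 21 cells, against 418, and 317, 317 and 342 control cells, against 325. The day 21 cells gained may be those of the early B cluster (300 and 0 cells), which was not traced. The ratio included 1 for hepatocyte-like (1.01-fold, 0.8004 to 1.27), conventional dendritic-like (1.16-fold, 0.823 to 1.63) and plasmacytoid dendritic-like cells (0.954-fold, 0.662 to 1.38), but the direction differed between settings (log2 ratios down to -0.82 for hepatocyte-like cells with each cell's own markers, -0.56 for conventional dendritic-like cells among haematopoietic classes, and up to 0.28 for plasmacytoid dendritic-like cells under the stricter filter). Unnamed clusters held 21.4% of day 21 cells, with 2.21% in the low-UMI endothelial cluster. Endothelial-like cells with that cluster made up 11.98 against 46.3%. Counting named haematopoietic classes alone, the neutrophil-like log2 ratio was 3.67 against 4.44 among all cells, the Kupffer-like -1.37, the T-like -2.05 and the NK/ILC1-like -2.28, and the basophil/mast-like 0.49. That total leaves out every unnamed cluster, including the granule-gene cluster with 927 day 21 cells. The neutrophil-like value was 5.11 with all granulocytic clusters combined, the monocyte/macrophage-like 3.16 at a coarser clustering against 4.18, and the stellate-like -1.10 without a cell filter against -1.90. Under the stricter filter the Kupffer-like ratio was -2.18 and the endothelial-like -2.42, against -0.59 and -1.56.

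In the endothelial-like, Kupffer-like and stellate-like classes, most cells of the day 21 library lay in clusters of their own. Cluster 5 held 95.4% of its endothelial-like cells, against clusters 0 and 9 in the control and at day 4. Cluster 11 held 83.0% of its Kupffer-like cells, against clusters 7 and 13. Cluster 24 held 97.7% of its stellate-like cells, against clusters 17 and 23. Depth was also lower, with medians of 1969 against 7550 UMIs in Kupffer-like, 2657 against 5726 in endothelial-like and 1759 against 3695.5 in T-like cells. The median mitochondrial percentage per cell was higher in Kupffer-like (12.9 against 9.81%), endothelial-like (10.1 against 8.04%), T-like (10.9 against 9.25%) and B-like cells (13.2 against 10.3%). Neutrophil-like cells went the other way, with 2091 against 1402.5 UMIs and 5.28 against 7.52%. The neutrophil transcripts S100a8 or S100a9 were seen in 94.7% of day 21 T-like cells (92.6 to 96.4) and 1.198% of control T-like cells (0.518 to 2.35), a class that should lack them. In cells thinned to 1000 UMIs these shares were 81.8 and 0.313%. Free RNA was estimated at 18.2% of UMIs in Kupffer-like cells (3.14% in the control), 8.59% in endothelial-like (1.09%), 10.1% in T-like (2.23%), 21.8% in hepatocyte-like (5.62%) and 25.6% in stellate-like cells (19.9%). As at day 4, this estimate does not separate free RNA from mixed droplets. The examples below had at least 0.25 of the level of the class where the gene was highest in that library, and the same control library serves both comparisons.

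In endothelial-like cells at day 21, the adhesion list had a median log2 ratio of 1.19 (1.12 to 1.40, percentile 100), with 11 of 15 measured members at least 2-fold higher and 0 at least 2-fold lower. Sele, the leukocyte-capturing E-selectin (ENSMUSG00000026582, chromosome 1, 164048234 to 164057677, plus strand, GRCm38), had 3 UMIs in the control and 33 at day 21 (0.381 and 12.4 CPM, log2 ratio 4.83, 3.36 to 7.38). The other examples were P-selectin, Selp (13.7 and 155 CPM, 3.49, 3.19 to 3.82), von Willebrand factor, Vwf (31.6 and 141 CPM, 2.16, 1.92 to 2.39), and Vcam1 (61.9 and 202 CPM, 1.70, 1.52 to 1.88). IL6-STAT3 genes were higher (1.11, 1.04 to 1.24, percentile 100), with 7 of 12 measured members at least 2-fold higher and 0 at least 2-fold lower. They included the transcriptional regulator Bcl3 (6.10 and 54.3 CPM, 3.15, 2.67 to 3.66), the feedback inhibitor Socs3 (63.3 and 424 CPM, 2.75, 2.59 to 2.90) and the kinase Jak2 (59.3 and 149 CPM, 1.33, 1.13 to 1.52). Inflammatory cytokine genes stood at 1.13 (0.93 to 1.40, percentile 100), with Csf1 (157 and 313 CPM, 0.997, 0.87 to 1.12), the growth factor of macrophages. Their median was 1.89 with no minimum of UMIs. Immediate early and dissociation-linked genes were higher (1.37, 1.32 to 1.43, percentile 100), with Nr4a1 (8.26 and 50.2 CPM, 2.60, 2.17 to 3.05) and Egr1 (202 and 682 CPM, 1.75, 1.65 to 1.85). Junb belongs to this list and to the IL6-STAT3 list. S phase genes were higher (0.77, 0.41 to 1.23, percentile 99.9), as Mcm5 (9.91 and 31.3 CPM, 1.66, 1.196 to 2.12) and Slbp (62.8 and 158 CPM, 1.33, 1.14 to 1.52) show.

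Type I interferon genes were lower in endothelial-like cells at day 21 (-1.02, -1.2 to -0.90, percentile 0), with 0 of 13 measured members at least 2-fold higher and 7 at least 2-fold lower. Examples were Ifit3 (45.9 and 7.55 CPM, -2.57, -3.33 to -1.955), Ifit2 (73.5 and 34.3 CPM, -1.09, -1.43 to -0.78) and Bst2 (468 and 220 CPM, -1.09, -1.22 to -0.96). Interferon gamma genes had a median of -0.34 (-0.43 to -0.08, percentile 0.0600) with members on both sides. Of these Cxcl10 (27.6 and 63.8 CPM, 1.21, 0.91 to 1.51) and Irf1 (80.2 and 141 CPM, 0.82, 0.63 to 1.002) were higher and Cxcl9 (123 and 56.2 CPM, -1.12, -1.39 to -0.88) lower. Among angiocrine factors (0.26, 0.12 to 0.30, percentile 87.8), the hepatocyte growth factor gene Hgf (20.8 and 256 CPM, 3.61, 3.37 to 3.87) was higher and Bmp6 (127 and 60.0 CPM, -1.07, -1.33 to -0.83), which induces the iron hormone hepcidin, lower. Fatty acid and cholesterol genes were higher (0.52, 0.30 to 0.58, percentile 99.9), with the cholesterol exporter Abca1 (68.2 and 125 CPM, 0.88, 0.67 to 1.08). The lipid carrier Fabp4 (1649 and 846 CPM, -0.96, -1.03 to -0.90) was lower. Nuclear-encoded oxidative phosphorylation genes were lower (-0.24, -0.31 to -0.18, percentile 2.04), with Ndufb8 (228 and 151 CPM, -0.59, -0.75 to -0.43). Mitochondrially encoded genes stood at 0.25 (0.24 to 0.27, percentile 87.4), with mt-Co1 (11770 and 17340 CPM, 0.56, 0.54 to 0.58). Glycolysis genes (0.31, 0.23 to 0.51, percentile 93.6) included Ldha (158 and 298 CPM, 0.92, 0.79 to 1.05). Hypoxia genes (0.09, -0.05 to 0.21, percentile 50.3) included Ddit4 (202 and 25.3 CPM, -2.99, -3.37 to -2.65), which was lower. Sinusoidal scavenger receptors as a list were close to all genes (0.12, 0.08 to 0.15, percentile 71.3), with Msr1 (368 and 512 CPM, 0.47, 0.38 to 0.57) higher and Cd209b (25.0 and 12.1 CPM, -1.03, -1.64 to -0.51) lower.

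The largest ratios in endothelial-like cells were those of Cnmd (1.27 and 120.0 CPM, 6.49, 5.66 to 7.64), which encodes the angiogenesis inhibitor chondromodulin, Il17ra (4.45 and 118 CPM, 4.72, 4.23 to 5.28), a receptor of interleukin 17, and the transcription factor gene Myc (1.78 and 45.3 CPM, 4.63, 3.87 to 5.58). After them came Hspa1b (6.99 and 113 CPM, 4.01, 3.60 to 4.46) and Nav2 (8.13 and 103 CPM, 3.65, 3.27 to 4.08). The Cnmd log2 ratio was 8.20 under the stricter filter and 5.68 as a mean over cells, and that of Myc 5.56 in thinned cells. The smallest were those of the histone gene Hist1h4d (29.1 and 1.89 CPM, -3.81, -5.58 to -2.70) and of Cyp26b1 (339 and 24.5 CPM, -3.78, -4.17 to -3.43), a retinoic acid hydroxylase that also helped define cluster 9. They were followed by the histone gene Hist1h1e (74.6 and 5.28 CPM, -3.77, -4.70 to -3.06). The clock output factor Hlf (55.8 and 4.15 CPM, -3.69, -4.76 to -2.89) and the glucocorticoid-induced factor Klf15 (49.4 and 4.53 CPM, -3.39, -4.41 to -2.63) completed them. Subtracting free RNA moved the log2 ratios of Hist1h4d and Hist1h1e to -7.17 and -7.56, and that of Klf15 was -2.42 in thinned cells.

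Kupffer-like cells at day 21 had lower type I interferon genes (-0.62, -0.74 to -0.40, percentile 0), with 0 of 15 measured members at least 2-fold higher and 3 at least 2-fold lower. They included Ifit3 (68.5 and 25.7 CPM, -1.40, -1.92 to -0.94), Bst2 (285 and 142 CPM, -1.003, -1.22 to -0.799) and Irf7 (907 and 526 CPM, -0.78, -0.89 to -0.68). Interferon gamma genes were higher (0.36, 0.23 to 0.59, percentile 95.9, and 0.27 to 0.68 over the other settings), with Iigp1 (36.1 and 96.7 CPM, 1.42, 1.08 to 1.77) and Irf1 (52.9 and 123 CPM, 1.22, 0.93 to 1.51). Kupffer identity genes, many of them also markers of the class, had a median of 0.30 (0.26 to 0.43, percentile 97.8), with the scavenger receptor Marco (86.4 and 232 CPM, 1.42, 1.21 to 1.65) and the transcription factor Spic (58.1 and 128 CPM, 1.14, 0.86 to 1.42). The C-type lectin gene Clec4f, a marker of these cells (ENSMUSG00000014542, chromosome 6, 83644542 to 83656187, minus strand, GRCm38), stood at 6882 and 5087 CPM (log2 ratio -0.44, -0.47 to -0.40). S phase genes were higher (0.64, 0.31 to 0.83, percentile 99.3), with Mcm2 (13.2 and 25.1 CPM, 0.93, 0.29 to 1.56), but stood at 0.18 with free RNA subtracted. Iron and haem handling genes were lower (-0.37, -0.41 to -0.17, percentile 0.8), with the ferritin light chain Ftl1 (10650 and 5251 CPM, -1.02, -1.05 to -0.99) and the biliverdin reductase Blvrb (588 and 308 CPM, -0.93, -1.07 to -0.79). Immunosuppressive myeloid genes stood at -0.43 (-0.52 to -0.02, percentile 0.475), with Il10 (41.0 and 6.73 CPM, -2.55, -3.64 to -1.73), and at 0.01 among members with 100 or more UMIs. Inflammatory cytokine genes (0.20, 0.06 to 0.58, percentile 73.6) turned to -0.56 without members under 0.25 of the level in the highest class, and lipid-associated macrophage genes (0.18, 0.02 to 0.31, percentile 77.0) to -0.71 with free RNA subtracted. MHC class II genes (0.11, -0.07 to 0.19, percentile 58.2) turned to -0.35 without members under 0.25 of the level in the highest class, with the invariant chain Cd74 (2853 and 1862 CPM, -0.62, -0.67 to -0.56) lower.

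The largest ratios in Kupffer-like cells were those of Hspa1b, a stress-induced chaperone gene (ENSMUSG00000090877, chromosome 17, 34956436 to 34959238, minus strand, GRCm38, 5.23 and 114 CPM, log2 ratio 4.41, 3.76 to 5.21), and its near copy Hspa1a (9.91 and 132 CPM, 3.71, 3.22 to 4.28). Next were Nabp1 (16.5 and 101 CPM, 2.60, 2.18 to 3.06), the C-type lectin-related gene Clec2d (21.5 and 121 CPM, 2.49, 2.11 to 2.89) and Cd300lb (12.9 and 65.5 CPM, 2.33, 1.83 to 2.87). In thinned cells the log2 ratios of Hspa1b and Hspa1a were 6.46 and 2.91, and those of Clec2d and Cd300lb 3.12 and 3.30. The smallest were those of Tgfb3 (94 UMIs in the control and 2 at day 21, -4.09, -7.47 to -2.51), Cdkn1a (277 and 16.5 CPM, -4.04, -4.67 to -3.52) and Cxcl2 (991 and 105 CPM, -3.24, -3.47 to -3.02). The ubiquitin ligase subunit Fbxo32 (169 and 19.0 CPM, -3.13, -3.72 to -2.63) and Gpt2 (79.3 and 11.0 CPM, -2.81, -3.62 to -2.16), the mitochondrial alanine aminotransferase, came next. The log2 ratio of Tgfb3 was -2.67 with 5 counts added, and that of Cdkn1a -4.83 with free RNA subtracted, and that of Gpt2 -2.04 in thinned cells. Cxcl2 and Cdkn1a were among the 5 smallest ratios of this class at both days.

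Neutrophil-like cells at day 21 lay in clusters 2, 8 and 10 (36.7, 34.3 and 29.1%), against cluster 2 for 98.2% of those in the control. The median log2 ratio of all genes in the class was -1.06 and moved to -0.14 with median-of-ratios size factors, so lists are also given relative to it. Granule protein genes, many of them also class markers, had a median of 1.18 (1.06 to 2.39, percentile 100), or 2.23 relative to the median of all genes, and 1.18 with members at 0 set to their bound. Over the other settings their median ranged from 0.96 to 2.97. Ngp and Ltf, which encode secondary granule proteins, had 0 UMIs in the control and were at least 215-fold and 68.8-fold higher against a floor of 3 counts. With called doublets kept the log2 ratios of Ngp and Ltf were 1.54 and 1.98, and within cluster 2 alone 4.68 and 2.66. As at day 4, keeping doublets also changed the control cells of the class, to 57 from 54. Cluster 10, with 734 of the 2525 day 21 cells of the class and 0 control cells, carried most of both, with Ngp at 15590 and Ltf at 5173 CPM, against 1132 and 73.9 in cluster 8. In cluster 2 they stood at 176 and 43.1 CPM, against 119.6 and 48.7 in T-like cells, so the rise within that cluster is not separated from free RNA. Ly6g (13.2 and 1257 CPM, log2 ratio 5.98, 4.09 to 11.87) and the secreted factor gene Prok2 (13.2 and 1039 CPM, log2 ratio 5.71, 3.82 to 11.60) had 1 UMI each in the control, and the Ly6g ratio was 2.95 with doublets kept. The stefin gene Stfa3 was at least 32.1-fold higher, and Stfa3 also helped define cluster 10, as Prok2 did clusters 8 and 10. Glycolysis genes had a median of 0.59 (0.46 to 1.33, percentile 100), or 1.64 relative to the median of all genes, with Gapdh (212 and 952 CPM, 2.12, 1.47 to 2.98). The median was 0.05 with 5 counts added and 1.50 with size factors. With members at 0 at their bound it was 0.57.

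Inflammatory cytokine genes in neutrophil-like cells had a median of -2.04 (-2.38 to -1.196, percentile 1.57), or -0.99 relative to the median of all genes. Members included Ccl6 (1629 and 232 CPM, -2.82, -3.08 to -2.54) and Cxcl2 (1125 and 256 CPM, -2.15, -2.45 to -1.80). The median was 0.34 in cluster 2 alone and -1.13 with size factors. Type I interferon genes stood at -1.30 (-2.06 to -1.03, percentile 16.0), or -0.24 relative to the median of all genes, and at -0.07 in cluster 2 alone and -2.92 with 5 counts added. The antiviral gene Rsad2 (424 and 16.6 CPM, -4.69, -5.25 to -4.06) had the smallest ratio, followed by Fam114a1 (146 and 6.07 CPM, -4.63, -5.57 to -3.47) and the ribonuclease gene Rnase6 (146 and 6.07 CPM, -4.63, -5.57 to -3.47). Next came Elmsan1 (278 and 12.3 CPM, -4.52, -5.20 to -3.73) and the apoptosis gene Pmaip1 (119 and 6.22 CPM, -4.32, -5.32 to -3.04). Size factors raised these 5 log2 ratios by the shift of all genes, 0.92. In cluster 2 alone the Rsad2 log2 ratio was -2.90 and that of Pmaip1 -2.26. In simulated counts of this comparison 22% of genes with a planted 2-fold and 50% with a planted 4-fold increase had an interval on the right side of 0, as did 20% with a 2-fold and 42.1% with a 4-fold decrease.

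Stellate-like cells at day 21 had higher inflammatory cytokine genes (2.01, 1.37 to 2.48, percentile 100), with 10 of 13 measured members at least 2-fold higher and 1 at least 2-fold lower. They included Ccl2 (10.6 and 308 CPM, 4.85, 4.42 to 5.34) and Cxcl1 (15.04 and 77.0 CPM, 2.35, 1.90 to 2.83), and the median was 1.27 among members with 100 or more UMIs. Matrix and activation genes were higher (0.71, 0.62 to 0.85, percentile 100), with the protease inhibitor Timp1 (0.940 and 38.9 CPM, 5.21, 3.93 to 7.29) and fibronectin, Fn1 (198 and 772 CPM, 1.961, 1.83 to 2.09). IL6-STAT3 genes (0.73, 0.63 to 0.99, percentile 100) included Socs3 (46.3 and 259.6 CPM, 2.49, 2.23 to 2.74) and Osmr (43.9 and 142 CPM, 1.70, 1.40 to 1.99), the latter a receptor of oncostatin M. Adhesion genes (0.82, 0.59 to 1.05, percentile 100) included Selp (3.29 and 57.6 CPM, 4.09, 3.30 to 5.06) and Icam1 (54.5 and 123 CPM, 1.17, 0.88 to 1.46). Immediate early and dissociation-linked genes were higher (1.02, 0.94 to 1.10, percentile 100), with Egr1 (241 and 679.6 CPM, 1.49, 1.37 to 1.62). Type I interferon genes were lower (-0.76, -0.86 to -0.60, percentile 0), with Usp18 (48.6 and 20.8 CPM, -1.203, -1.83 to -0.67) and Ifi44 (81.0 and 36.1 CPM, -1.16, -1.62 to -0.74).

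Hepatocyte-like cells at day 21 had higher acute phase genes (2.87, 2.48 to 3.36, percentile 100), with 8 of 10 measured members at least 2-fold higher and 0 at least 2-fold lower. Saa2, a serum amyloid A gene (ENSMUSG00000057465, chromosome 7, 46751790 to 46754313, plus strand, GRCm38), had 8 UMIs in the control and 340 at day 21 (9.72 and 626 CPM, log2 ratio 5.92, 5.01 to 7.23), beside Saa1 (47.4 and 1028 CPM, 4.42, 3.97 to 4.95) and Orm1 (422 and 938 CPM, 1.15, 0.95 to 1.35). The list median was 1.2 with free RNA subtracted, 3.83 as a mean over cells and 4.12 in hepatocyte cluster 18 alone. Hnf4a itself stood at 130.1 CPM in the control and 134 CPM at day 21 (log2 ratio 0.05, -0.40 to 0.49). Cluster 32, which is deeper and also carries cholangiocyte markers, held 30.1% of the class in the control and 16.7% at day 21. Values of the whole class therefore mix 2 kinds of cells in unequal parts. HNF4A-linked genes were lower (-0.44, -0.51 to -0.40, percentile 0.0200), including Cyp2e1 (1861 and 466 CPM, -1.995, -2.19 to -1.80), Apob (1335 and 518 CPM, -1.36, -1.56 to -1.18) and Cyp7a1 (43.8 and 14.7 CPM, -1.50, -2.89 to -0.44). The urea cycle enzyme Otc (153 and 446 CPM, 1.54, 1.23 to 1.86) was higher, and the list median was 0.26 under the stricter filter. Glycolysis genes were higher (0.62, 0.38 to 0.78, percentile 99.5), with Tpi1 (179 and 315 CPM, 0.82, 0.49 to 1.15). IL6-STAT3 genes stood at 0.74 (0.46 to 0.91, percentile 99.8), with Cebpb (356 and 549 CPM, 0.62, 0.39 to 0.86), and at 0.05 in hepatocyte cluster 32 alone. Urea cycle genes stood at 0.46 (0.19 to 0.73, percentile 94.0), with Ass1 (655 and 1347 CPM, 1.04, 0.88 to 1.203), and at 1.04 in cluster 18 alone.

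In T-like cells at day 21 the median log2 ratio of all genes was 0.20 and moved to 0.04 with median-of-ratios size factors. G2/M genes had a median of 1.15 (1.003 to 1.34, percentile 100), or 0.95 relative to the median of all genes, with Tpx2 (20.6 and 56.4 CPM, 1.45, 0.91 to 2.003) and Nusap1 (28.0 and 72.6 CPM, 1.38, 0.91 to 1.85), and 1.74 under the stricter filter. S phase genes stood at 0.34 (0.19 to 0.69, percentile 80.5), or 0.14 relative to the median of all genes. The cycling T-like cluster held 8.14% of the class. Cytotoxic genes were higher (0.88, 0.58 to 1.07, percentile 100, or 0.68 relative to the median of all genes), with the transcription factor Tbx21 (11.7 and 36.8 CPM, 1.65, 0.95 to 2.38) and Ifng (27.2 and 67.5 CPM, 1.31, 0.83 to 1.80). They stood at 0.20 among members with 100 or more UMIs. Inhibitory receptor genes (0.57, 0.24 to 0.73, percentile 94.3, or 0.37 relative to the median of all genes) included Ctla4 (60.6 and 89.7 CPM, 0.57, 0.19 to 0.93) and the regulatory T cell factor Foxp3 (10.9 and 23.9 CPM, 1.14, 0.33 to 1.95). Interferon gamma genes were higher (0.55, 0.34 to 0.70, percentile 99.7, or 0.35 relative to the median of all genes), with Gbp7 (87.8 and 168 CPM, 0.93, 0.65 to 1.21) and Irf1 (62.2 and 108 CPM, 0.805, 0.46 to 1.15). Type I interferon genes were lower (-0.42, -0.69 to -0.13, percentile 0.0300, or -0.62 relative to the median of all genes), with Ifi27l2a (872 and 741 CPM, -0.24, -0.35 to -0.12). Their median was -0.13 among members with 100 or more UMIs. Naive lymphocyte genes stood at -0.15 (-0.22 to -0.06, percentile 7.70), or -0.35 relative to the median of all genes, with S1pr1 (213 and 167 CPM, -0.35, -0.60 to -0.12). The median of all genes was also 0.21 in B-like cells, and 0.04 with median-of-ratios size factors.

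**Figure D2:**
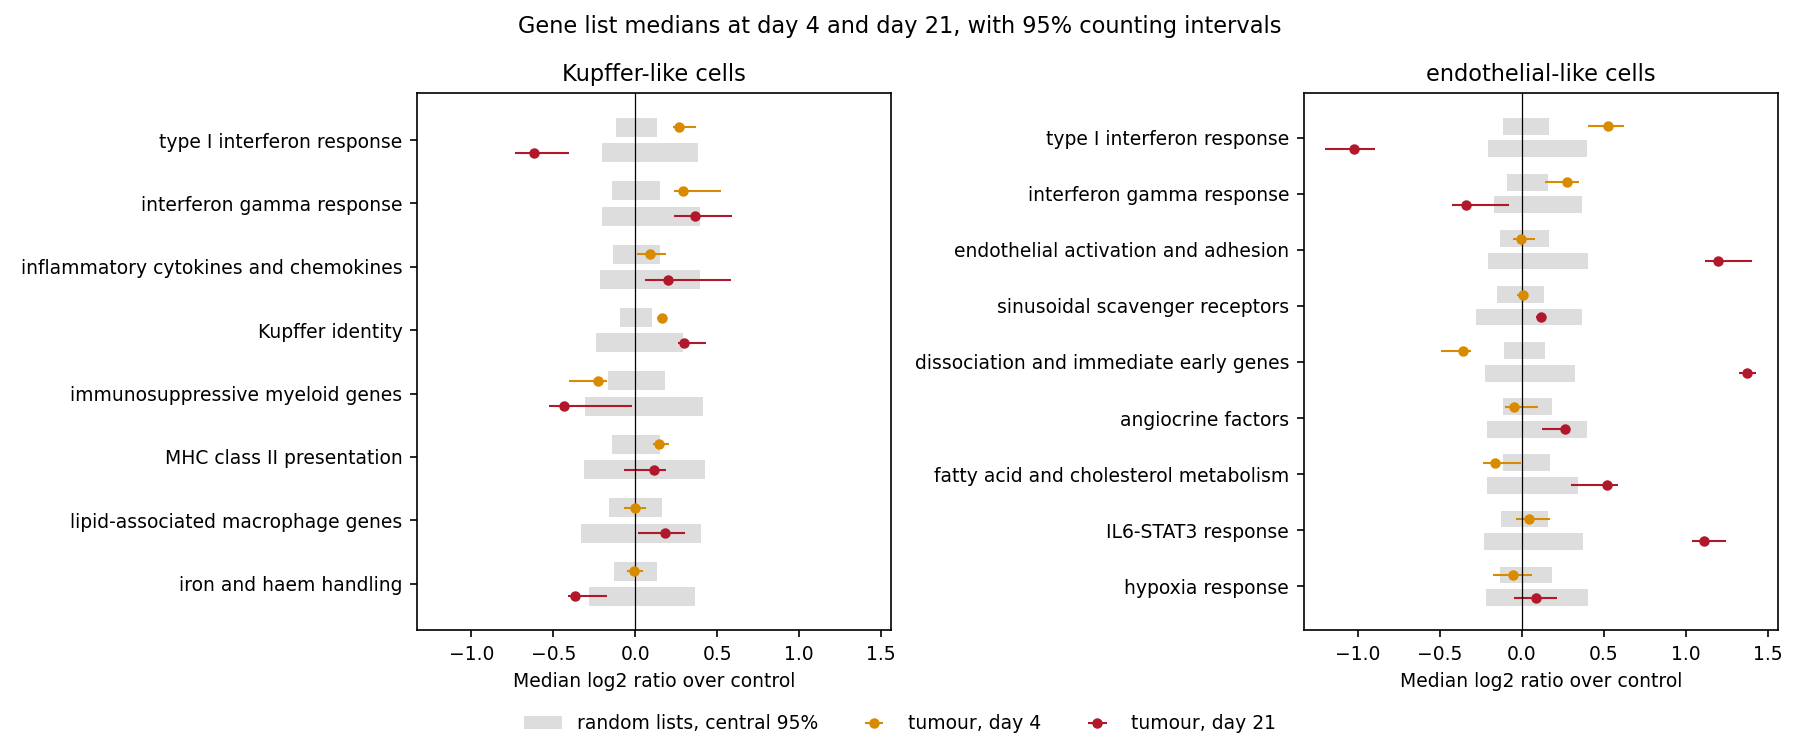
Median log2 ratio over control of gene lists in Kupffer-like (left) and endothelial-like cells (right), at day 4 and day 21, with 95% counting intervals as bars and the central 95% of random lists in grey. Endothelial adhesion genes sit at -0.01 and 1.19, and type I interferon genes at 0.52 and -1.02.

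The comparison of day 21 with day 4 sets the later stage against the earlier, without the control library. Neutrophil-like cells had a 7.12-fold (6.17 to 8.21), monocyte/macrophage-like cells a 25.5-fold (16.8 to 38.7), in cluster 14 alone a 12.6-fold (8.28 to 19.2), and neutrophil precursor-like cells a 169.6-fold (49.0 to 587) higher share at day 21, while the shares of Kupffer-like (0.397-fold, 0.362 to 0.435) and endothelial-like cells (0.354-fold, 0.329 to 0.381) were lower. Medians of type I interferon genes were lower at day 21 than at day 4 in endothelial-like (-1.44, -1.60 to -1.31, percentile 0), stellate-like (-1.05, -1.16 to -0.83, percentile 0), T-like (-0.87, -1.14 to -0.71, percentile 0), Kupffer-like (-0.84, -0.97 to -0.65, percentile 0) and hepatocyte-like cells (-0.71, -1.04 to -0.27, percentile 0). Endothelial adhesion genes were higher (1.43, 1.23 to 1.58, percentile 100). The 2 libraries also differ in age and in time since injection, and these values were not recomputed under other settings.

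**Figure D3:**
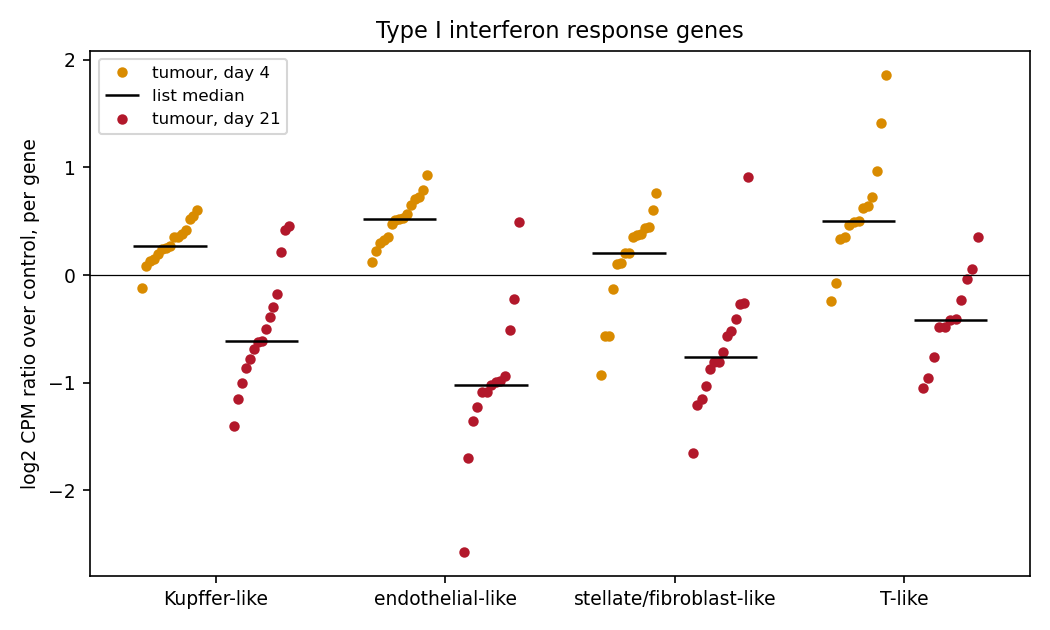
Log2 ratio over control of single members of the type I interferon list at day 4 and day 21, by class, with 1 point per gene and the list median marked. The medians in Kupffer-like cells are 0.27 and -0.62.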

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

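Of the results in this part, the bounds that picked them and both tests named below were chosen after the results had been seen. The differences between groups were not tested, because each group holds 1 library, and the same control library enters both comparisons.

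Type I interferon genes lay on opposite sides of the control at the 2 days, with medians of 0.27 at day 4 and -0.62 at day 21 in Kupffer-like, 0.52 and -1.02 in endothelial-like, 0.50 and -0.42 in T-like (-0.13 with a minimum of 100 UMIs), and 0.21 and -0.76 in stellate-like cells. Lower depth at day 21 was tested by thinning every cell to 1000 UMIs, and the endothelial median stayed at -1.06. Thinning keeps the expected proportions within each cell, so that value cannot decide on depth. Free RNA mixed into the class was tested by subtracting its estimate, and the median was -1.04. The latter value argues against free RNA as the whole cause in endothelial-like cells, the only class with a prediction. A lower interferon response late in tumour growth may be a candidate explanation. Depth, age, time of collection and the single control library stay open.

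Other values also lay on opposite sides of the control at day 4 and day 21. The log2 ratio of the Kupffer-like share was 0.74 and -0.59. Shares depend on one another, however. Per endothelial-like cell, Kupffer-like cells were 1.74 and 1.95 times the control, on the same side at both days. Interferon gamma genes in endothelial-like cells stood at 0.28 and -0.34. Immediate early and dissociation-linked genes stood at -0.36 and 1.37 in endothelial-like cells, and at -0.52 and 1.02 in stellate-like cells. With 1 library per group, a difference in dissociation cannot be told apart from the tumour for this list. Fatty acid and cholesterol genes in endothelial-like cells stood at -0.17 and 0.52, but in cells thinned to 1000 UMIs the day 4 median was 0.0192, on the same side as day 21. Among barcodes that the report's comparisons leave out, those with under 200 genes and over 50% haemoglobin UMIs made up 9.19% (8.60 to 9.80) of the day 4 library, above the 3.53% of the control, and 3.27% at day 21.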

How the results depend on the processing

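The same direction as reported was found in 190 of 208 values of class shares under other settings, 875 of 912 values of the 81 list medians and 500 of 500 values of the 60 named genes. Of the shares, 165 stayed within the reported interval, 40 left it and 3 took the opposite sign although the reported interval excluded 0, against 758, 140 and 14 for the lists and 453, 47 and 0 for the genes. Over all 387 list and class pairs, 3668 of 4080 values kept the direction and 72, in 49 pairs, took the opposite sign in that way. The G2/M list in stellate-like cells at day 4 had no value in thinned cells, and the cytotoxic list in T-like cells at day 4 none without members under 0.25 of the highest class. Added gene lists and the comparison of day 21 with day 4 were not rerun. Counts were few in neutrophil-like cells, with 75523 UMIs in the control. For the values below the cause was not tested.

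Without a cell filter, log2 share ratios at day 4 were -1.44 for monocyte/macrophage-like, -0.23 for endothelial-like, -0.20 for stellate-like and -1.01 for B-like cells. At day 21 they were 3.60 for monocyte/macrophage-like, -0.42 for Kupffer-like, -1.71 for endothelial-like, -1.10 for stellate-like, -0.39 for hepatocyte-like, 0.33 for B-like and -1.09 for T-like cells. With each cell's own markers, endothelial-like, hepatocyte-like and NK/ILC1-like cells stood at -0.19, 0.42 and -0.0419 at day 4. Endothelial-like, hepatocyte-like, conventional dendritic-like and B-like cells then stood at -1.86, -0.82, -0.34 and 0.0674 at day 21. With the low-UMI cluster added, endothelial-like cells stood at -0.22 and -1.95. Keeping doublets gave -0.16 for NK/ILC1-like cells at day 4.

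At day 21 the stricter filter gave -2.18 for Kupffer-like, -2.42 for endothelial-like, -2.16 for stellate-like, -2.75 for B-like, -2.05 for T-like and -2.19 for NK/ILC1-like cells. Resolution 0.5 gave 4.83 for neutrophil-like and 3.16 for monocyte/macrophage-like cells, and resolution 2 gave 0.0836 for B-like cells. Among haematopoietic classes, the values were 3.67 for neutrophil-like, 3.41 for monocyte/macrophage-like, -1.37 for Kupffer-like, -0.56 for conventional dendritic-like, -0.84 for plasmacytoid dendritic-like, -1.50 for B-like, -2.05 for T-like, -2.28 for NK/ILC1-like and 0.49 for basophil/mast-like cells. All granulocytic clusters combined gave 5.11 for neutrophil-like cells, cluster 14 alone 3.16 for monocyte/macrophage-like cells, and equal cell numbers 3.19 for monocyte/macrophage-like and -1.09 for T-like cells.

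Among list medians at day 4, keeping doublets gave -0.74 for granule genes in neutrophil-like and -0.0786 for HNF4A-linked genes in hepatocyte-like cells, and the stricter filter -0.0315 for the latter. Thinning gave 0.40 for type I interferon genes in Kupffer-like and 0.0192 for fatty acid genes in endothelial-like cells, and size factors -0.0314 for scavenger receptors. At day 21 Kupffer identity genes stood at 0.21 with doublets kept, 0.56 thinned, 0.21 with size factors, 0.59 as a mean over cells and 0.47 with free RNA subtracted. Endothelial adhesion genes stood at 1.06 thinned, 1.12 with size factors and 1.07 with a minimum of 100 UMIs, and scavenger receptors at 0.0386 with size factors and 0.20 with free RNA subtracted. Lipid-associated genes in Kupffer-like cells stood at -0.36 thinned, -0.71 with free RNA subtracted, -0.28 without members under 0.25 of the highest class, -0.29 with a minimum of 100 UMIs and -0.12 with none. Without members under 0.25 of the highest class, inflammatory genes in Kupffer-like cells stood at -0.56 and immunosuppressive genes at 0.00795, and the latter at 0.00795 also with a minimum of 100 UMIs. The stricter filter gave 0.26 for HNF4A-linked genes at day 21, and cluster 2 alone 0.34 for inflammatory genes in neutrophil-like cells.

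Other list medians outside the reported interval and under 0.5 of the reported value are as follows. At day 4, thinning gave -0.0909 for immunosuppressive genes in Kupffer-like cells and 0.62 for granule genes in neutrophil-like cells. Means over cells gave 0.60 for granule genes in neutrophil-like cells, and -0.0816 for naive and 0.27 for S phase genes in T-like cells. In neutrophil-like cells type I interferon genes stood at 0.49 with a minimum of 100 UMIs, 0.48 with 5 counts added and 0.40 under the stricter filter. Cluster 2 alone gave 0.46 for granule genes and keeping doublets 0.15 for acute phase genes. At day 21, free RNA subtracted gave 0.18 for S phase genes in Kupffer-like and 1.2 for acute phase genes in hepatocyte-like cells. Keeping doublets gave -0.0215 for immunosuppressive genes in Kupffer-like and 0.15 for urea cycle genes in hepatocyte-like cells. In neutrophil-like cells, 5 counts added gave 0.0537 for glycolysis genes, and type I interferon genes stood at -0.38 with size factors and -0.0714 in cluster 2 alone. Thinning gave -0.20 for HNF4A-linked genes in hepatocyte-like cells, and 0.30 for cytotoxic and 0.24 for inhibitory receptor genes in T-like cells. A minimum of 100 UMIs gave 0.20 for cytotoxic genes in T-like and 0.0268 for inflammatory genes in Kupffer-like cells. Hepatocyte cluster 18 alone gave -0.22 for HNF4A-linked and 0.24 for IL6-STAT3 genes, and cluster 32 alone 0.0501 for the latter. The stricter filter gave 0.12 for mitochondrially encoded genes in endothelial-like cells.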

Other observations

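The gene lists of this paragraph and the next were chosen after many of their members' values had been seen, as were the tests of the endothelial share and the 7-gene test, while the other 2 tests of neutrophil transcripts were set beforehand. Medians of glucocorticoid-responsive genes lay below 0 at day 4 in the 8 classes measured, while some members lay above 0, such as Ddit4 in NK/ILC1-like (0.12) and Fkbp5 in neutrophil-like cells (0.24). The medians were -0.73 in Kupffer-like, -0.99 in endothelial-like, -0.98 in neutrophil-like, -0.95 in stellate-like, -0.71 in T-like, -1.11 in B-like, -0.90 in NK/ILC1-like and -0.76 in hepatocyte-like cells. At day 21 they stood at -1.58 in Kupffer-like, -0.81 in endothelial-like, -1.17 in stellate-like, -0.90 in NK/ILC1-like, -0.52 in B-like and -0.31 in hepatocyte-like cells, but at -0.03 in T-like cells. In neutrophil-like cells the day 21 median was -2.25, where the median of all genes was -1.06. As Ddit4, Klf15 and Cdkn1a had drawn attention to the list, its percentiles (0 to 1.27 at day 4) are not independent evidence.

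Heat shock genes had day 4 medians of 0.32 in Kupffer-like, 0.67 in endothelial-like, 0.61 in stellate-like, 0.47 in T-like, 0.70 in NK/ILC1-like and 0.51 in hepatocyte-like cells, and of 0.20 in neutrophil-like (percentile 93.1) and 0.20 in B-like cells (percentile 92.6). At day 21 they stood at 1.51 in NK/ILC1-like, 0.95 in T-like, 0.74 in B-like, 0.46 in endothelial-like and 0.42 in hepatocyte-like cells, but at 0.16 in Kupffer-like and -0.02 in stellate-like cells. In neutrophil-like cells they stood at -1.01 (percentile 37.3), close to the median of all genes there, -1.06. Clock genes of the evening arm, such as Per1, Dbp and Hlf, stood at -0.89 in endothelial-like, -0.92 in stellate-like, -0.54 in Kupffer-like and -0.77 in hepatocyte-like cells at day 21, but at -0.05 in T-like and 0.04 in B-like cells. At day 4 they were -0.16, -0.07, -0.24, -0.22, -0.32 and -1.07 in the same order of classes, with only 3 measured members in B-like cells at either day. Those of the morning arm, with 3 measured members each, stood at 0.23 in Kupffer-like and 0.32 in T-like cells at day 21 and at 0.19 and -0.25 at day 4, and the time of day of collection was not stated.

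Transcripts of neutrophils lay in classes that should lack them at day 21, with S100a8 or S100a9 in 94.7% of T-like cells. Granulocytes caught in the same droplets would leave most T-like cells without them, which that share argues against. If the source were 1 pool of free RNA, the proportions of these genes would match between classes, and over 7 genes in T-like, B-like and endothelial-like cells the median absolute log2 residual was 0.135, with a largest value of 0.520. With NK/ILC1-like cells included only S100a8 and S100a9 could be compared (0.00599), and that value decides nothing, because any granulocyte source would keep the ratio of these 2 genes. Free RNA from lysed granulocytes may be the source in the 3 classes, while uptake of granulocyte material, which would keep the same proportions, and biological explanations were not tested.

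The endothelial-like share was lower at day 21 than in the control. Dilution by incoming haematopoietic cells alone would leave the number of hepatocyte-like cells per endothelial-like cell as it was. This number was 2.97 times the control (2.32 to 3.81), with 1.95 for Kupffer-like, 1.77 for B-like, 1.22 for T-like and 0.787 for stellate-like cells. At day 4 the numbers were already 2.06 (1.62 to 2.63) for hepatocyte-like and 1.74 for Kupffer-like cells, but 0.615 for B-like and 0.692 for T-like cells. The endothelial-like share at day 4 was nevertheless 0.960-fold, or -0.22 as a log2 ratio with the low-UMI cluster counted, so dilution stays open. With the low-UMI cluster counted as endothelial the day 21 share was 0.259 of the control's, so the loss of shallow cells to that cluster does not account for it. A lower yield of endothelial cells in dissociation and an altered vascular bed may both give these values, and neither was tested.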
